A study of Bradyrhizobium diazoefficiens USDA 110 with 6 samples.

How the data were processed

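RNA from paraquat-treated and untreated cultures of Bradyrhizobium diazoefficiens was compared on 6 two-colour spotted arrays, 3 biological replicates each hybridised in both dye orientations, per the labels. Per the labels' protocols, cells received 5 mM paraquat for 10 min, 30 ug of total RNA was reverse transcribed with random hexamers, and 5 ug of cDNA was labelled. The deposited table holds 1 log ratio per probe and array, taken as log2. The log base is not stated: log2 makes the largest value a 25.4-fold ratio, natural log would make it 106-fold, and log10 would need 46195-fold, so a natural log scale is not excluded and folds assume log2. The scanner, background correction and within-array normalization are not given in the sources used here. Column medians lay between -0.09 and -0.05. Between 1043 and 3448 of the 8480 probes had no value on an array, 106 had none on any, and 3700 had one on all 6.

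The platform annotation gave 1 gene symbol for 8462 probes, several for 0 and none for 18. Only 1469 probes had a symbol that differed from the locus tag, so genes without such a name could not enter the gene lists. Rows of the same gene were averaged, giving 8269 genes. The probes' locus tags matched 0 entries of the reference gene table, so no coordinates are given. Arrays of opposite orientation correlated above 0, so the table had already been turned to 1 direction. That positive means paraquat over untreated is likely, from the word order of the array titles, and is not stated.

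The design fixed before the data were examined was a limma fit of 3 replicate means against 0. The columns of replicates 2 and 3 turned out to hold identical values wherever both were measured, in 5509 of 5509 probes with paraquat in Cy5 and 6125 of 6125 with paraquat in Cy3. In all 4620 probes with the needed values, the swap difference of these columns was also -0.5 times that of replicate 1, within 0.0001. Each of these columns can therefore be written as the mean of a replicate 1 array and 1 shared set of values. That shared set was recovered by subtraction, and each gene entered as 2 values, the replicate 1 swap mean and the recovered value. By construction, the mean of these 2 values equals the swap mean of the deposited replicate 2 and 3 columns. Writing the columns as such means is not the only reading the relation allows, and the dye orientation of the recovered value is unknown. The p-values hold only if the recovered value is independent of replicate 1.

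This 2-value fit was chosen after the data were seen and after the counts of several fits were known. The fit fixed beforehand, with 3 replicates, called 2152 genes. Counting replicates 2 and 3 once without recovery called 1213, and treating all 6 columns as independent called 2285. The 2-value fit called 189. In simulated data without change, averaging the second value with the first put 30.4% of genes under an unadjusted p of 0.05 and called 288 genes, against 5.15% and 0 with independent values.

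Tests used limma 3.58.1 in R 4.3.3 (lmFit, eBayes) with Benjamini-Hochberg adjustment and a threshold of 0.05. Of the genes, 4547 had all values needed. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, with an estimated correlation, and with fry. Tested on simulated data of 4547 genes with 200 changed, the paraquat fit called 50.0% of genes changed by 1 on the log2 scale, 96.0% of those changed by 2, 98.0% by 3 and 100% by 4, and 3.91% of its calls were false. Both simulated values had the same change and spread. The 2 real values had SDs over genes of 0.516 and 0.797 and correlated at r = 0.684, so these shares need not hold for the data. In a simulation of lists, 10 of 10 lists shifted by 1 and 0 of 40 unshifted ones were called with the preset correlation. Its genes were drawn independently, so it says nothing about false calls for lists whose genes vary together. With 1 residual degree of freedom, the estimated correlation and fry's directional test each called 0 of 10 at shifts of 1 and 3, so they could hardly pass here, and fry's mixed test called 1 of 10 at a shift of 1 and 10 of 10 at 3. The number of arrays limits the precision.

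Of 32 gene lists fixed by product or symbol, 6 had no symbols to match (LysR, TetR and AcrR, and MarR, MerR and SoxR regulators, arabinose and gluconate use, ABC transporters, transposases), because the annotation holds no products. The remaining lists were translated to gene symbols after the genes of largest change had been seen. Of these, 5 had under 3 measured genes and 21 were tested. A further 7 lists, denitrification among them, were added after the data were seen and adjusted within a family of 28. Named genes were the 15 largest and 15 smallest mean ratios among called genes with 1 sign on every array, up to 4 further called members per list or else the 2 of smallest p, and a fixed set of oxidative stress and repair genes. The text prints a part of these.

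Alternatives covered the replicate block, dye orientation, centring and scaling, gene filter, single rows, variance model, test and threshold. Most were run on the 2 values in place of 3 replicates. The replicate block fit used 3 values, the 2 replicate 1 arrays and the recovered value. The 6-column fit, the 3-replicate fit and the fit with replicates 2 and 3 counted once used the deposited columns. Errors of single genes are limma's moderated SE unless called plain. Same-numbered arrays are a technical swap of 1 pair of extracts, per the labels, which is where the pairing comes from. The block used a correlation of 0.738 estimated by moments, as the repeated columns make a check of the pairing across all 3 numbers void.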

Results

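The response of the soybean symbiont Bradyrhizobium diazoefficiens to a short shock with paraquat, a redox-cycling compound that generates superoxide, was measured on spotted arrays. Treated cultures received 5 mM paraquat for 10 min and were compared with untreated cultures. The series holds 6 arrays, 3 with paraquat in Cy5 and 3 with paraquat in Cy3, labelled as 3 biological replicates. Between 59.3% and 87.7% of the 8480 probes had a value on each array. Replicates 2 and 3 held identical values and were counted as 1 sample, and their columns also shared values with replicate 1, so each gene rests on n = 2 values. Positive log2 ratios mean higher with paraquat, a direction that is likely from the array titles but not stated, and the log2 base is assumed.

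Which genes changed within minutes of paraquat was the first question. Genes for respiration at low oxygen and on nitrate were among the largest rises. The cbb3 oxidase genes fixN, fixO, fixQ and fixP, which encode a high-affinity terminal oxidase, had log2 ratios of 3.59 ± 0.33, 3.83 ± 0.34, 3.89 ± 0.21 and 2.63 ± 0.20 (limma's moderated SE, n = 2 values). The moderated SE, given with each ± for a gene, borrows its spread from all genes; the plain SE of the 2 values was 0.62, 0.66, 0.27 and 0.25 for these genes, and it exceeded the moderated one in 123 of the 189 called genes. The periplasmic nitrate reductase gene napD reached 4.21 ± 0.38 (plain SE 0.76), from 3.45 in replicate 1 and 4.97 in the recovered value. The unnamed locus blr6074 and carQ (bll1028), named for a sigma factor, had mean ratios of 4.63 ± 0.37 and 4.44 ± 0.25. Their order differed between the values, with 3.90 and 4.02 in replicate 1 and 5.35 and 4.85 in the recovered value. Among the largest falls were the unnamed loci bsl2574 at -3.76 ± 0.53 (plain SE 1.11), bll4354 at -3.30 ± 0.24 and blr4701 at -3.30 ± 0.38. These had -2.65, -2.92 and -2.54 in replicate 1 and -4.87, -3.69 and -4.06 in the recovered value, so their order also differed.

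Of 4547 genes tested, 189 were called at an adjusted p under 0.05 by limma, 137 higher and 52 lower. All 189 changed at least 2-fold, the smallest by 1.02 on the log2 scale. The fit could hardly call smaller changes, so this says little about the size of the response. The recovered value was larger in size than the replicate 1 value in 168 of the 189, with a slope of 1.31 over these genes, and for 22 genes the fold in replicate 1 alone differed from the mean by over 1.5 times. The mean equals the deposited swap mean of replicates 2 and 3, and the recovered value is extrapolated from it away from replicate 1. Calling genes on this mean favours larger recovered values, so the 168 and the slope need not describe the genes. The coproporphyrinogen oxidase gene hemN (bll7086), of heme synthesis, had a log2 ratio of 3.70 ± 0.19. Further large rises were the unnamed loci blr4638 at 3.99 ± 0.27, bll5655 at 3.64 ± 0.26, bll3998 at 3.58 ± 0.17 and bsr6066 at 3.76 ± 0.41, the last with 2.92 in replicate 1 and 4.59 in the recovered value. The flagellar export gene fliQ (bsl5811) stood at -2.45 ± 0.34 (-1.80 in replicate 1 and -3.11 in the recovered value), and ilvC, of branched-chain amino acid synthesis, at -1.77 ± 0.18. This 2-value fit was chosen after the counts of several fits were seen: the fit fixed before the data were examined, which counts the repeated columns as 3 replicates, called 2152 genes, 726 higher and 1426 lower, and counting replicates 2 and 3 once without removing the shared values called 1213. A fit with the replicate block called 88 genes lower in place of 52, and a plain one-sample statistic per gene called 0, with 354 genes at an unadjusted p under 0.05 against 891 by limma. With 1 residual degree of freedom, the plain statistic could hardly call any gene. With only the paraquat in Cy3 array of replicate 1, the calls of bsl2574, fliQ, coxB, sucC, clpB, rpoH2 and rpsS were lost at adjusted p of 0.0548 to 0.0638 by limma.

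**Figure D1:**
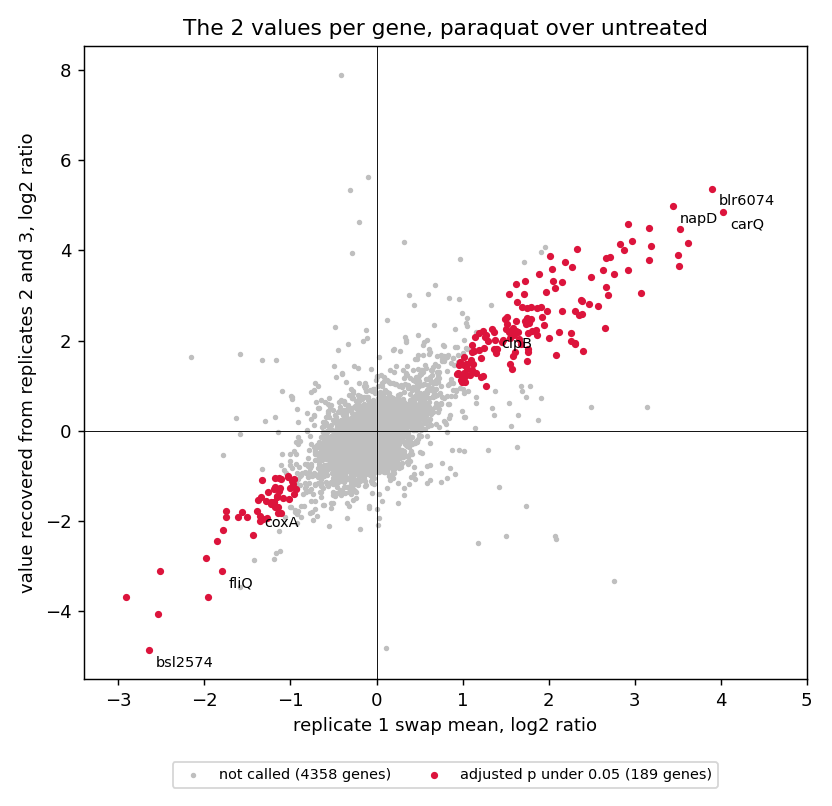
Each point is 1 of 4547 genes, with the log2 ratio of the replicate 1 swap mean on the horizontal axis and the value recovered from the columns of replicates 2 and 3 on the vertical axis. The 189 called genes, in red, lie in the upper right (137 higher) and lower left (52 lower).

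Whether gene lists moved together was tested for 21 lists, whose symbols were matched after the largest changes had been seen. Among cytochromes and terminal oxidases, 8 of 22 measured genes rose, 2 fell and 12 did not pass, with 15 higher and 2 lower when adjusted over the list alone. The cytochrome gene cycB rose by 3.24 ± 0.22, whereas coxA and coxB, subunits of the aa3-type oxidase, fell by 1.58 ± 0.19 and 1.46 ± 0.23 on the log2 scale. In the nitrogen fixation list, 9 of 25 genes rose and 16 did not pass, with 10 higher when adjusted over the list alone. The genes fixN, fixO, fixP and fixQ belong to both lists and make up 4 of the rises in each. Its rising members were fix genes: fixG reached 3.25 ± 0.31, and the regulator genes named fixK at bll7696, bll2757 and bll6061 reached 2.33, 2.22 and 2.08. The 7 measured nif genes gave 0 calls by limma, 1 at an unadjusted p under 0.05, and log2 ratios between -0.22 and 0.44.

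Ribosomal protein genes gave 10 lower calls and 41 that did not pass among 51, with 15 lower when adjusted over the list alone. Most of the calls lay close together by locus number. A run of 6 called neighbours went from bsl5382 to bll5387, and rpsS (bsl5396), rplD (bll5399) and rplC (bll5400) lay near it. Other ribosomal protein genes in this stretch did not pass, and rpsP (blr0482) was called outside it. The genes rpmD, rpsE and rpsS fell by 1.77 ± 0.17, 1.71 ± 0.19 and 1.42 ± 0.19. Subunit genes of NADH dehydrogenase I had a median log2 ratio of -0.56, with 12 of 12 below 0. By limma 0 of them were called, 0 when adjusted over the list alone, and 6 had an unadjusted p under 0.05. ATP synthase genes had a median of -0.43, with 7 of 8 below 0, 0 called, and 3 lower when adjusted over the list alone. Among 6 sigma factor genes, carQ and rpoH2, a heat shock sigma factor gene, rose, the latter by 1.21 ± 0.17.

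By camera with the preset correlation, 6 of the 21 lists were called, with adjusted p of 1.90e-08 for cytochromes and oxidases, 1.37e-07 for nitrogen fixation, 0.000249 for ribosomal proteins, 0.0113 for NADH dehydrogenase I, 0.0199 for sigma factors and 0.0285 for ATP synthase. These p-values assume that preset correlation, which the simulation with independent genes did not test. For all 6 the adjusted p = 0.823 with an estimated correlation, but with 1 residual degree of freedom that version called 0 of 10 simulated lists shifted by 1 or by 3, as did fry's directional test, so the loss under these says nothing about the lists. Under fry's mixed test, which called 1 of 10 simulated lists at a shift of 1 and 10 of 10 at 3, 0 of the 6 were called, with adjusted p from 0.193 to 0.263. The sigma factor call was lost without the 30 genes of largest change (adjusted p = 0.202) and after centring and scaling (0.0620), over a range of 4.23e-05 to 0.202 across alternatives with the preset correlation. The ATP synthase call was lost with the replicate block (adjusted p = 0.0928) and with replicates 2 and 3 counted once (0.0504), over a range of 0.0137 to 0.0928 across the same alternatives.

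**Figure D2:**
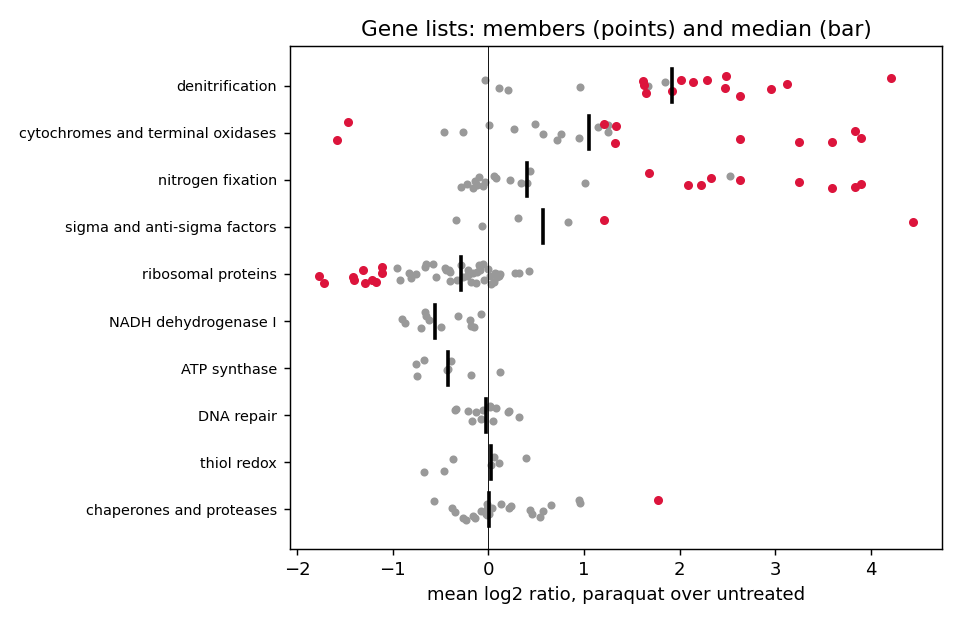
Each point is a gene, placed by its mean log2 ratio of paraquat over untreated, with called genes in red and a black bar at each list's median. Points of the denitrification list, added after the data were seen, lie mostly to the right, with a median of 1.92, and the ribosomal protein median lies at -0.28.

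The oxidant removal list had 2 measured genes and was too small to test. No probe carried the symbol soxR, katG, katE, sodB, sodC, sodM or fpr, so any such genes could not be found by name. The superoxide dismutase gene sodF had a log2 ratio of -0.48 ± 0.21 (adjusted p = 0.301 by limma), and osmC one of 0.01. The alkyl hydroperoxide reductase gene ahpC had a value on 1 array and was not tested. The 14 DNA repair genes gave 0 calls by limma and 0 at an unadjusted p under 0.05, with recA at -0.35 and lexA at -0.34. The 7 thiol redox genes gave 0 calls and 1 at an unadjusted p under 0.05. The ferredoxin-NADP reductase gene mvrA stood at 0.36, and the iron regulators irr and fur at 0.41 and -0.09. The disaggregase gene clpB (blr1404) rose by 1.78 ± 0.25, 1 of 26 chaperone and protease genes called, with 3 higher when adjusted over the list alone, and dnaK stood at 0.57. The groEL copies bll2059, blr5626 and blr7533, which are open to cross-hybridisation, had ratios of 0.04, -0.23 and -0.57.

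Of the other lists, TCA cycle genes gave 1 call, sucC, which fell by 1.05 ± 0.17, and efflux genes 1, tolC, which fell by 1.41 ± 0.17. The polyhydroxyalkanoate synthase gene phbC rose by 2.52 ± 0.30. Among 39 flagella and motility genes 1 was called, fliQ, with 4 higher and 10 lower when adjusted over the list alone. Chemotaxis, nodulation, exopolysaccharide, NADPH supply, iron and heme uptake, translation factor, flavin and quinone reductase, carbon dioxide fixation and cold shock lists, 79 genes in all, gave 0 calls by limma and 15 genes at an unadjusted p under 0.05. Adjusted over the list alone, 1 of 3 carbon dioxide fixation genes was higher, cbbA at 1.39 ± 0.27.

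Whether the dye orientation changed a gene's ratio could not be tested across replicates, and its size is measured in replicate 1 alone, because the swap differences of replicates 2 and 3 are fixed by those of replicate 1. The fit written for it gave 0 calls by limma, with 2 genes at an unadjusted p under 0.05, and says nothing about dye effects.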

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

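The 2-value fit, the merged columns, the filters for all 6 arrays and for discordant genes, the lists without the 30 largest changes and the turned orientation were chosen after the data were seen. The 189 called genes (137 higher, 52 lower) became 2152 (726, 1426) in the fit fixed beforehand with 3 replicates, 1213 (494, 719) with replicates 2 and 3 counted once, and 2285 (768, 1517) with 6 columns as independent values; these repeat values, which narrows their spread by construction. Counts were 102 (83, 19) with only paraquat in Cy3, 388 (275, 113) after centring and scaling, and 309 (211, 98) at unadjusted p and 2-fold. The cause was not tested. A plain statistic gave 0 (0, 0), but with 1 residual degree of freedom it could hardly call any gene. Lower calls moved to 88 with the replicate block, of 258 in all and 170 higher, and to 34 after median centring. Of 64 called genes followed one by one, 15 lost their call with only paraquat in Cy3, 6 after median centring, 5 with the wider gene filter, 4 with only Cy5 and 4 with robust eBayes, at adjusted p of 0.0508 to 0.0959 by limma. Among genes printed, coxB and sucC were lost in all but the last, bsl2574 with Cy3 and robust eBayes, nirK in all but Cy5, leuA with Cy3 and the wider filter, and fliQ, clpB, rpoH2, rpsS and ilvH with Cy3. Without replicate 2 or 3 the count was 196 to 218 (139 to 145 higher, 57 to 73 lower), which shows only the effect of missing values, since both hold the same values, and without replicate 1 no test is left. With the wider gene filter 8 lists were called, and with replicates 2 and 3 counted once 1 further list gained a call. The 6 called lists became 0 with an estimated correlation, 0 with directional fry and 0 with mixed fry. The first 2 rest on 1 residual degree of freedom and called 0 of 10 simulated shifted lists, so they decide little about stability. ATP synthase lost its call with the replicate block (adjusted p = 0.0928) and with replicates 2 and 3 counted once (0.0504), of a range of 0.0137 to 0.0928 with the preset correlation. Sigma factors lost theirs after centring and scaling (0.0620) and without the 30 largest changes (0.202), of a range of 4.23e-05 to 0.202. The dye count of 0 became 1079 with the orientation of replicates 2 and 3 turned, and neither is a test, since those differences are fixed by replicate 1. A wider gene filter for the dye difference was not run. Signal over background was not analysed here.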

Other observations

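The tests of denitrification and oxidase genes, of the repeated columns and of the flagellar genes were chosen after the values were seen; that of neighbouring genes was written before its result was computed, though neighbours among the largest changes had been seen. Denitrification genes, which serve respiration on nitrogen oxides, gave 13 higher calls among 19 measured, a list added after the data were seen. The genes napA, napB and napC had log2 ratios of 3.12, 2.49 and 2.63, the nitrite reductase gene nirK 2.28 (1.54 in replicate 1 and 3.02 in the recovered value), norC and norB of nitric oxide reductase 2.01 and 1.62, nosZ of nitrous oxide reductase 2.48, and the regulator gene nnrR 2.95. Of the 6 not called, norE, norD and napE had 1.67, 0.96 and 1.84, and nosY, nosL and nosX 0.20, 0.11 and -0.04. The napE mean came from 3.15 in replicate 1 and 0.54 in the recovered value. Because the list was chosen after the values were seen, none of its p-values tests whether its genes rose. By camera the list's adjusted p was 3.56e-18 with the preset correlation over 28 lists. This p also assumes that preset correlation, whereas members such as napD, napA, napB and napC are neighbours by locus number and may vary together. With an estimated correlation the adjusted p was 0.790. That version called 0 of 10 simulated shifted lists and could hardly pass with 2 values per gene. By fry's mixed test, which called 1 of 10 simulated lists at a shift of 1 and 10 of 10 at 3, the adjusted p was 0.180. The heme synthesis genes hemA and hemN1 (bll2007) rose by 2.92 and 2.47, while the list as a whole had 3 of 11 called, a median of -0.25 and an adjusted p of 0.283. In branched-chain amino acid synthesis ilvC, ilvH and ilvD (bll4763) fell by 1.77, 1.67 and 1.46, leuA rose by 1.12, and the list's adjusted p was 0.340.

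The 23 genes of denitrification and the cbb3 oxidase had a median log2 ratio of 2.13, and 17 were called higher. For the replicate 1 ratios alone, dye bias is argued against by a median absolute dye effect of 0.0589, beside a median ratio of 1.81 there. The dye effect in the recovered value could not be measured, since its dye orientation is unknown. The median of 2.23 after centring decides nothing, since centring of the arrays moves every gene alike. A hypothesis is that oxygen ran low during the treatment, since low oxygen is known to raise these genes. Hydrogenase genes, which low oxygen also raises, had a median of -0.096, but they need further signals, so this leaves the hypothesis open. Oxygen was not measured, and an effect of paraquat and a difference in aeration between treated and untreated cultures cannot be told apart.

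The columns of replicates 2 and 3 were identical in 100% of the probes measured in both, which argues against 3 separately measured replicates in the table. Their swap difference was -0.5 times that of replicate 1 in 4620 of 4620 probes, a value that may come from averaging each with the replicate 1 array of the other orientation. The replicate 3 array with paraquat in Cy5 held 7194 values. Only 5522 of those probes had a value on the replicate 1 array with paraquat in Cy3, so the others lack the array they would be averaged with. The reading was checked only in the 4620 probes with all needed values. Which processing step did this, and whether the shared values hold 1 or more biological replicates, stays open.

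Flagellar genes parted by position. The 10 genes with locus numbers from 5800 to 5899 had a mean log2 ratio of -1.27 ± 0.74 (SD over genes) and all 10 were below 0, while the 22 genes from 6800 to 6899 had a mean of 0.41 ± 0.29 with 19 above 0, or 20 after centring. The difference was -1.68, and it was -1.20 in the replicate 1 swap mean alone, so the recovered value alone does not make it. The limits of both groups were chosen after the values were seen, so no p is given for it, and 7 of the 39 listed genes lie outside them, 6 below 0. Among these flgD (blr6997) at -1.13 and fliN (blr7002) at -0.97 lie just past the second group but go with the first, and flhA (bll2207) is at -1.03, from 0.01 in replicate 1 and -2.08 in the recovered value. Also outside both groups, flaA at -0.08 and pomA at -0.01 are below 0 but above the median of -0.09 over genes tested. With flgD and fliN joined to the second group the difference was -1.56. Whether both gene groups respond differently cannot be told apart from the choice of the groups on these values; 1 of the 32 genes was called by limma, with 20 at an unadjusted p under 0.05, and neighbouring genes are not independent.

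Over 2101 adjacent pairs of genes on the same strand the log2 ratios correlated across genes with r = 0.631, and over 942 adjacent pairs on opposite strands with r = 0.270. The difference was 0.362 (two-sided permutation test, p = 0.0001, the smallest that 10000 permutations can give). Consecutive pairs share a gene and are not independent, so this p may overstate the evidence. The difference goes with shared transcription of neighbours, and adjacent printing of probes was not tested. Runs of called neighbours included blr4657 to blr4660, of which only blr4658 has a symbol, glk, at 1.60 to 3.10, and bll7627 to blr7629, which have none, at 1.96 to 2.29. By its locus tag blr7629 lies on the other strand, so shared transcription on 1 strand does not cover that whole run.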
